A study of Mus musculus with 45 samples.

How the data were processed

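RNA from heart, liver and muscle of 6-week-old mice was hybridised to 45 arrays, 5 for each of 3 tissues and 3 fasting times, taken from the sample titles. Per the labels' protocols, RNA was extracted with TRIzol and RNeasy columns and had an integrity number above 7. The arrays carried 62976 spots, 59305 of them non-control, and were read in the Cy3 channel with Agilent Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09, per the file headers. The deposited intensity values are spot signals on a linear scale, background-subtracted by that software and not yet scaled between arrays. A table of the whole series, deposited by the authors, holds log2 values, with column medians per group between 5.47 and 5.52. Each of its 45 columns correlated best with its own array, with r of at least 0.996. The submitters' processing notes name R 3.4.0 and limma, and the background correction and normalization behind that table are not given in the sources used here.

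Probe positions are those printed with the probes, on build mm9 (NCBI37). Gene names were brought up to date through a table of RefSeq names (assembly GRCm38.p6), of which no coordinates were used. Of 55681 probes, 27656 were named by accession, 3401 by symbol, 321 by synonym, and 24303 kept the name in the file. Together they gave 34779 gene names, and 3614 spots carried different names in different annotations of the same design. Probes without a gene symbol were tested but not named.

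The main values were log2 of the processed signal minus the 75th percentile of each array, with spots of one probe averaged and control spots and outlier spots left out. A probe entered where it was well above background on at least 4 of 5 arrays in at least 1 group, and a gene was read from its brightest probe. This left 18507 genes in heart, 17991 in liver and 19218 in muscle. Each tissue was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on 15 arrays), with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences between tissues were tested as interactions. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over lists and comparisons of a tissue, with the estimated correlation and fry as alternatives. There were 52 lists, 36 of pathways and 16 of cell type markers, with 1155 genes, and a list needed 5 tested members. Camera sets a list against the other genes, so a constant shift between arrays drops out of its test. The R packages statmod 1.5.0 and arrow 21.0.0 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used.

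The groups, tests, gene lists, rule for named genes and most alternatives were chosen before the data were examined. For 24 and 48 h against 0 h the rule named the 6 largest rises and falls whose groups did not overlap, up to 2 genes in each direction known only by a bound, 18 core genes of fasting, and up to 4 called members of each list described. Some of the genes that the rule named are not reported here. Between 24 and 48 h it named 4 in each direction, between tissues 3, and over all tissues 8. A bound sets the bright group's mean against the mean of the lowest signal well above background, or the dim probe's own value where higher, on each array of the dim group. Which lists are described was settled after their values were seen, and so were the genes of iron metabolism in the closing section.

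Each tissue had its own 2 slides and scan day, so tissue and batch cannot be told apart for levels. Slides were tested as a block and within each slide. Inside the 24 h groups, limma called 0 genes between slides in any tissue, but 3 arrays against 2 cannot rule out a slide effect. Genes under an unadjusted p of 0.05 were 6.87%, 3.59% and 5.67% in heart, liver and muscle. In simulated data with 200 changed genes, the 24 h comparison recovered 61.2%, 92.5% and 100% of genes changed by 0.5, 1 and 2 log2 units in heart, 58.2%, 85.1% and 98.5% in liver, and 43.3%, 77.6% and 95.5% in muscle. False calls were 6 of 175, 10 of 171 and 7 of 151. In the simulated interactions at 48 h, 43.3%, 83.6% and 95.5% were recovered between liver and heart, 41.8%, 77.6% and 100% between liver and muscle, and 38.8%, 82.1% and 98.5% between heart and muscle, with 16 of 164, 14 of 160 and 12 of 158 false calls.

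The alternatives tried were other background corrections and scalings, other detection filters, other probes of a gene, array weights, a trended and robust variance, blocks for slide and replicate number, smaller and larger sets of arrays, stricter thresholds, the authors' table and leaving out each replicate. Those added after the data were seen are named in the closing section. No genome sequence was used here.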

Results

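Messenger RNA was measured in heart, liver and muscle of 6-week-old mice fasted for 0, 24 or 48 h, with 5 arrays for each tissue and time. The comparisons ask how each organ responded, how this moved with time and how far organs shared it. Of 59305 non-control spots, between 24133 and 30458 stood well above background on an array, and saturated spots numbered 0. The heart arrays had 27947 ± 890 such spots (mean ± SD, n = 5) at 0 h, 27486 ± 743 at 24 h and 25501 ± 934 at 48 h. The liver arrays had 27981 ± 2459, 26764 ± 862 and 26230 ± 873, and the muscle arrays 28784 ± 1477, 27948 ± 680 and 28449 ± 1014. The series design gives 5 mice per group, so the p-values measure the spread between these samples.

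Each tissue lay on 2 slides of its own. The first held all 0 h arrays with replicates 1 to 3 of 24 h, and the second held replicates 4 and 5 of 24 h with all 48 h arrays. Changes are log2 differences with their SE, and a gene rose or fell where limma gave an adjusted p under 0.05. The value "by slide" that follows a change comes from the fit with slide as a block. For gene lists, a second adjusted p "if estimated" comes from the test with an estimated correlation between genes. For 24 h against 0 h and for 48 h against 24 h the value by slide equals the difference within the slide that both groups shared. The 0 h and 48 h arrays never shared a slide. Every gene listed among the largest rises and falls had all 5 arrays of one time above all 5 of the other, and passed by slide too, as did each core gene called unless said otherwise. Counts of list members adjusted over the list alone are given where they differ from those adjusted over all genes. Positions are those of the probes on build mm9, and the part of the gene that a probe covers was not analysed here.

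**Figure D1:**
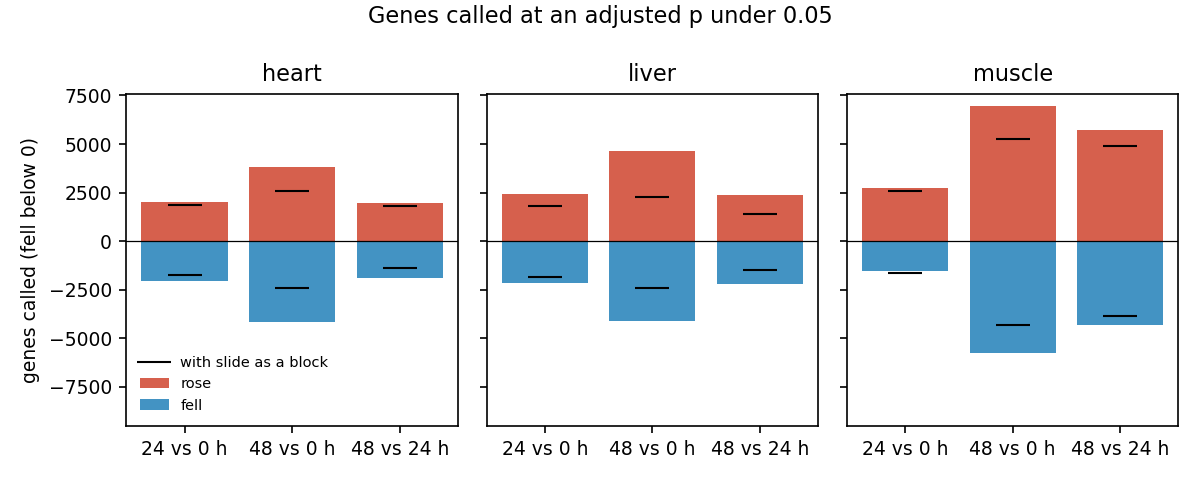
Number of genes that rose (up) and fell (down) at an adjusted p under 0.05 in each tissue and comparison, in genes. Black lines give the numbers with slide as a block. Muscle at 48 h had the tallest bars, with 6953 genes up and 5734 down, against 3800 and 4160 in heart and 4629 and 4132 in liver.

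After 24 h without food, the lists of muscle atrophy genes, targets of the fatty acid sensor PPAR and glucocorticoid-responsive genes stood higher in heart and those of collagen and cholesterol synthesis lower, and of these the muscle atrophy call alone held with an estimated correlation. Mt2, a metal-binding metallothionein (chromosome 8, 96697371 to 96697430), went from 3.68 ± 0.40 to 6.52 ± 0.37 log2 units above the array's 75th percentile (SD, n = 5), a 7.13-fold rise with an adjusted p of 1.58e-06. Tfrc, the receptor that brings transferrin-bound iron into cells (chromosome 16, 32632255 to 32632314), went from 1.71 ± 0.18 to -1.74 ± 0.24, an 11-fold lower level with an adjusted p of 1.22e-09. Pdk4, the kinase that shuts off pyruvate dehydrogenase (chromosome 6, 5433441 to 5433500), went from 5.13 ± 0.53 to 7.43 ± 0.74, a 4.95-fold rise with an adjusted p of 0.000119.

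The largest heart rises at 24 h were those of Mt2 (2.84 ± 0.21, 3.06 by slide), Angptl4, an inhibitor of lipoprotein lipase (2.53 ± 0.49, 2.66 by slide), and Txnip, which binds thioredoxin (2.46 ± 0.16, 2.65 by slide). Cdkn1a, the cell cycle inhibitor p21, rose by 2.36 (2.19 by slide) and Pdk4 by 2.31 (2.40 by slide). After Tfrc (-3.45 ± 0.13, -3.58 by slide), the largest falls were Rtn4r, the Nogo receptor (-2.42, -2.74 by slide), Plekhh1 (-2.27, -2.34 by slide), Itgb6, an integrin subunit (-2.11, -2.18 by slide), Mdga1 (-1.95, -2.15 by slide) and Dbh, the enzyme that makes noradrenaline (-1.78, -1.96 by slide). At 24 h Rtn4r was well above background on 1 of 5 arrays and Mdga1 on 4. A gene not well above background on any array of a group has only a bound, the bright group's mean over the dim group's detection floor. On that basis Rnf39 was at least 6.44-fold higher and Cdo1, cysteine dioxygenase, at least 2.94-fold higher at 24 h. Ccl12, a chemokine, was at least 3.15-fold lower and Tafa3 at least 2.2-fold lower. The Ccl12 call had an adjusted p of 0.0234, and 0.0565 by slide. Among the 18 core genes of fasting, Fkbp5, a glucocorticoid-induced chaperone, rose by 2.03 and the uncoupling protein Ucp3 by 1.03. The muscle ubiquitin ligases Fbxo32 and Trim63 rose by 0.92 and 0.47. Cpt1a, which brings fatty acids into mitochondria, rose by 0.36, although another Cpt1a probe, at 0.13, did not pass. Trim63 had an adjusted p of 0.0122, and 0.0574 by slide. The log2 differences of Scd1 (-0.21), Srebf1 (-0.16), Igf1 (-0.15), G6pc (0.09) and Ppargc1a (0.05) did not pass, but another Ppargc1a probe did (0.34, adjusted p = 0.0224).

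Of 25 muscle atrophy genes tested in heart, 17 rose and 8 did not pass, among them Mt1 at 1.49 and Foxo3, a transcription factor of atrophy, at 1.47 on the rising side, and 19 rose when adjusted over the list alone. Their mean change was 0.75 (0.78 by slide), with an adjusted p of 1.48e-14, adjusted p = 0.049 with an estimated correlation. Among 25 glucocorticoid response genes 17 rose and 8 did not pass, with Fkbp5 at 2.03 and the zinc finger Zbtb16 at 1.81, and 19 rose adjusted over the list alone. The mean was 0.96 (0.92 by slide; adjusted p = 9.49e-14, 0.095 if estimated). PPAR targets outside oxidation rose in 12 of 18 and fell in 1, with Angptl4, Txnip, Pdk4 and the thioesterase Acot1 (1.71) leading. Their mean was 0.83 (0.87 by slide; adjusted p = 6.38e-08, 0.091 if estimated). White adipocyte markers moved with them. Of 7, 5 rose and 2 did not pass, with the hormone-sensitive lipase Lipe at 0.85 and Fabp4 at 0.62. The marker mean was 0.63 (0.55 by slide; adjusted p = 8.29e-05, 0.049 if estimated). Fatty acid oxidation genes rose in 8 of 31 and fell in 1 (9 and 1 over the list alone), with the peroxisomal enzyme Ehhadh at 1.21. Their mean was 0.16 (0.19 by slide; adjusted p = 0.000261, 0.429 if estimated).

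Antioxidant targets of NRF2 rose in 14 of 28, with Gclm of glutathione synthesis at 1.44 and Gsta2 at 0.73, and 17 rose and 3 fell adjusted over the list alone. The mean was 0.26 (0.30 by slide; adjusted p = 6.68e-05, 0.0807 if estimated). Autophagy and lysosome genes rose in 14 of 42 and fell in 3 (18 and 3 over the list alone), with the mitophagy receptor Bnip3 at 1.30 and the autophagy adaptor Sqstm1 at 1.0. Their mean was 0.24 (0.26 by slide; adjusted p = 4.04e-05, 0.12 if estimated). Collagen and matrix genes fell in 18 of 37 and rose in 1, led by Col15a1 at -1.56 and Col3a1 at -1.10. The mean was -0.38 (-0.41 by slide; adjusted p = 5.96e-06, 0.317 if estimated). Fibroblast and stellate cell markers fell in 6 of 14 and rose in 2, with a mean of -0.22 that did not pass (adjusted p = 0.282). Cholesterol synthesis fell in 9 of 22 and rose in 1 (11 and 1 over the list alone). Sqle, its squalene epoxidase, was at least 2.09-fold lower. The mean was -0.32 (-0.33 by slide; adjusted p = 0.00175, 0.12 if estimated). In total 4062 of 18507 genes passed at 24 h, 1990 up and 2072 down, and 222 changed at least 2-fold. With slide as a block 3650 passed, 1883 up and 1767 down, and within the first slide alone 3350, 1662 up and 1688 down.

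By 48 h the changes of slow myosin, heme oxygenase and apelin that had begun by 24 h were larger in heart, and MHC class II and cell cycle genes were lower as lists, calls that did not hold with an estimated correlation. Myh7, the slow beta-myosin heavy chain (chromosome 14, 55589581 to 55589640), went from 3.99 ± 0.19 to 5.4 ± 0.63 at 24 h and 8.42 ± 0.43 at 48 h (SD, n = 5), a 21.6-fold rise with an adjusted p of 2.96e-08. Hmox1, which breaks down heme (chromosome 8, 77624207 to 77624266), went from 0.21 ± 0.11 to 1.37 ± 0.58 and 3.81 ± 0.31, a 12.1-fold rise with an adjusted p of 3.97e-08. Apln, the peptide apelin (chromosome X, 45378593 to 45378652), went from 1.35 ± 0.24 to -0.41 ± 0.50 and -2.89 ± 0.75, with an adjusted p of 1.33e-07 at 48 h, when 1 of 5 arrays was well above background. Mt2 stood 24.2-fold above 0 h.

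The largest heart rises at 48 h were Mt2 (4.6 ± 0.21, 5.17 by slide), Myh7 (4.43 ± 0.26, 5.42 by slide), Hmox1 (3.60 ± 0.22, 4.49 by slide), Angptl4 (3.49, 3.83 by slide), Tcf23 (3.46, 3.87 by slide) and Pip5k1a (3.45, 3.69 by slide), and other probes of Hmox1 and Pip5k1a rose by 1.90 and by 0.52 and 0.25. The largest falls were Apln (-4.24 ± 0.31, -4.75 by slide), Itgb6 (-4.23, -4.39 by slide), Tfrc (-3.47, -3.79 by slide), Plekhh1 (-2.98, -3.14 by slide), Cx3cr1, a chemokine receptor of macrophages (-2.97, -2.54 by slide) and Dbh (-2.96, -3.40 by slide). At 48 h Itgb6 and Plekhh1 were well above background on 1 of 5 arrays and Cx3cr1 on 3. Serpina3n was at least 8.12-fold higher and Rnf39 at least 7.36-fold higher, while Rtn4r was at least 3.99-fold lower and Aplnr, the receptor of apelin, at least 3.96-fold lower. Core genes that rose included Pdk4 (3.33), Cdkn1a (2.59), Fkbp5 (2.38), Ucp3 (1.62), Fbxo32 (1.19) and Cpt1a (0.87). The growth factor Igf1 (-0.49) fell, and other Igf1 probes ranged from -0.70 to 0.04. Trim63 (0.59), Scd1 (-0.27), Srebf1 (-0.48) and G6pc (0.46) passed in the pooled fit only, with adjusted p by slide of 0.148, 0.219, 0.107 and 0.456. Ppargc1a, at 0.31, did not pass, but its other probe did (0.64, adjusted p = 0.000112).

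Muscle atrophy genes rose in 21 of 25 in heart at 48 h and fell in 1, with a mean of 1.11 (1.18 by slide; adjusted p = 1.08e-11, 0.049 if estimated). Glucocorticoid response genes rose in 20 of 25 and fell in 1, with Lcn2 at 2.76. The mean was 1.33 (1.25 by slide; adjusted p = 6.28e-10, 0.13 if estimated). NRF2 targets rose in 18 of 28 and fell in 4, with Gclm at 1.82, Gsta2 at 1.48 and the sulfiredoxin Srxn1 at 1.26. Their mean was 0.58 (0.67 by slide; adjusted p = 8.79e-06, 0.049 if estimated). Fatty acid oxidation rose in 22 of 31 and fell in 1, with Cpt1b at 0.68. The mean was 0.35 (0.42 by slide; adjusted p = 1.57e-06, 0.323 if estimated). PPAR targets rose in 13 of 18 and fell in 1, with Acot1 at 2.80 and Txnip at 2.92, and the white adipocyte markers had 5 of 7 up (5 up and 1 down over the list alone). The list means were 1.30 (1.41 by slide; adjusted p = 1.46e-07, 0.0912 if estimated) and 0.62 (0.41 by slide; adjusted p = 0.00909, 0.114 if estimated). Ribosome biogenesis genes rose in 27 of 40 and fell in 2 (28 and 2 over the list alone), led by Myc at 2.55 and Ddx21 at 1.05. Their mean was 0.38 (0.46 by slide; adjusted p = 8.31e-08, 0.109 if estimated). Autophagy genes rose in 22 of 42 and fell in 3 (22 and 4 over the list alone), with Bnip3 at 1.89 and Gabarapl1 at 1.61, and their mean was 0.33 (0.39 by slide; adjusted p = 0.000212, 0.161 if estimated).

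Collagen and matrix genes fell in 27 of 37 in heart at 48 h and rose in 4 (29 and 4 over the list alone). Col14a1 was at -2.49 and Col3a1 at -2.29, while Timp1, an inhibitor of matrix proteases, rose by 2.58. Col14a1 was then well above background on 1 of 5 arrays. The mean was -0.57 (-0.65 by slide; adjusted p = 5.87e-07, 0.277 if estimated). Fibroblast and stellate cell markers fell in 7 of 14 and rose in 3 (8 and 3 over the list alone), with a mean of -0.51 that did not pass (adjusted p = 0.0695; -0.58 by slide, adjusted p = 0.0538). All 6 MHC class II genes that passed among 7 fell, with H2-Eb1 at -1.75 and H2-Ab1 at -1.60, and interferon response genes fell in 17 of 33 (21 over the list alone), with Gbp3 at -1.32 and Isg15 at -0.98. The means were -1.19 (-1.23 by slide; adjusted p = 0.00251, 0.33 if estimated) and -0.51 (-0.50 by slide; adjusted p = 6.67e-05, 0.477 if estimated). Macrophage markers fell in 9 of 14 and rose in 1 (10 and 1 over the list alone), with Aif1 at -1.82. The marker mean was -0.40 (-0.43 by slide; adjusted p = 0.0179, 0.46 if estimated). Cell cycle genes fell in 14 of 24 and rose in 2, among them the cyclins Ccnb2, at least 2.02-fold lower, and Ccna2, at least 1.08-fold lower. Their mean was -0.80 (-0.91 by slide; adjusted p = 0.00141, 0.327 if estimated). The cardiac contractile and stress list passed in neither direction (adjusted p = 0.197), with Myh7, the stress marker Ankrd1 (1.59) and the natriuretic peptide Nppa (1.13) up and the gap junction gene Gja1 (-0.79) among 9 down. Its mean was 0.15, its median -0.18 and its test pointed down. In total 7960 genes passed at 48 h, 3800 up and 4160 down, with 765 at least 2-fold, and 5010 passed with slide as a block, 2580 up and 2430 down.

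Between 24 and 48 h, 3862 heart genes changed further, 1977 up and 1885 down. The largest rises were Myh7 (3.02, 3.61 by slide), Serpina3n (2.63, 2.79 by slide), Timp1 (2.61, 2.52 by slide) and Hmox1 (2.44, 2.98 by slide), and the largest falls Apln (-2.48, -2.78 by slide), Itgb6 (-2.11, -2.18 by slide), Rasl10a (-2.08, -2.43 by slide) and the imprinted gene Mest (-1.76, -1.83 by slide). The other Itgb6 probe, at -0.28, did not pass here (adjusted p = 0.527). Well above background were Serpina3n on 3 of 5 arrays at 24 h, and Apln, Itgb6 and Mest on 1 and Rasl10a on 3 at 48 h. Ribosome biogenesis genes rose in 21 of 40 and fell in 1, and NRF2 targets rose in 14 of 28 and fell in 3. Their means were 0.30 (0.35 by slide; adjusted p = 1.4e-10, 0.0865 if estimated) and 0.32 (0.38 by slide; adjusted p = 1.33e-05, 0.049 if estimated). Cell cycle genes fell in 10 of 24, with a mean of -0.69 (-0.75 by slide; adjusted p = 4.94e-05, 0.213 if estimated). In the slide block 3175 genes passed, 1787 up and 1388 down, and within the second slide alone 1489, 877 up and 612 down. The share of rises was 51.2% in the main scaling, 40.3% in the authors' table and 40.9% with the percentile taken over detected probes.

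**Figure D2:**
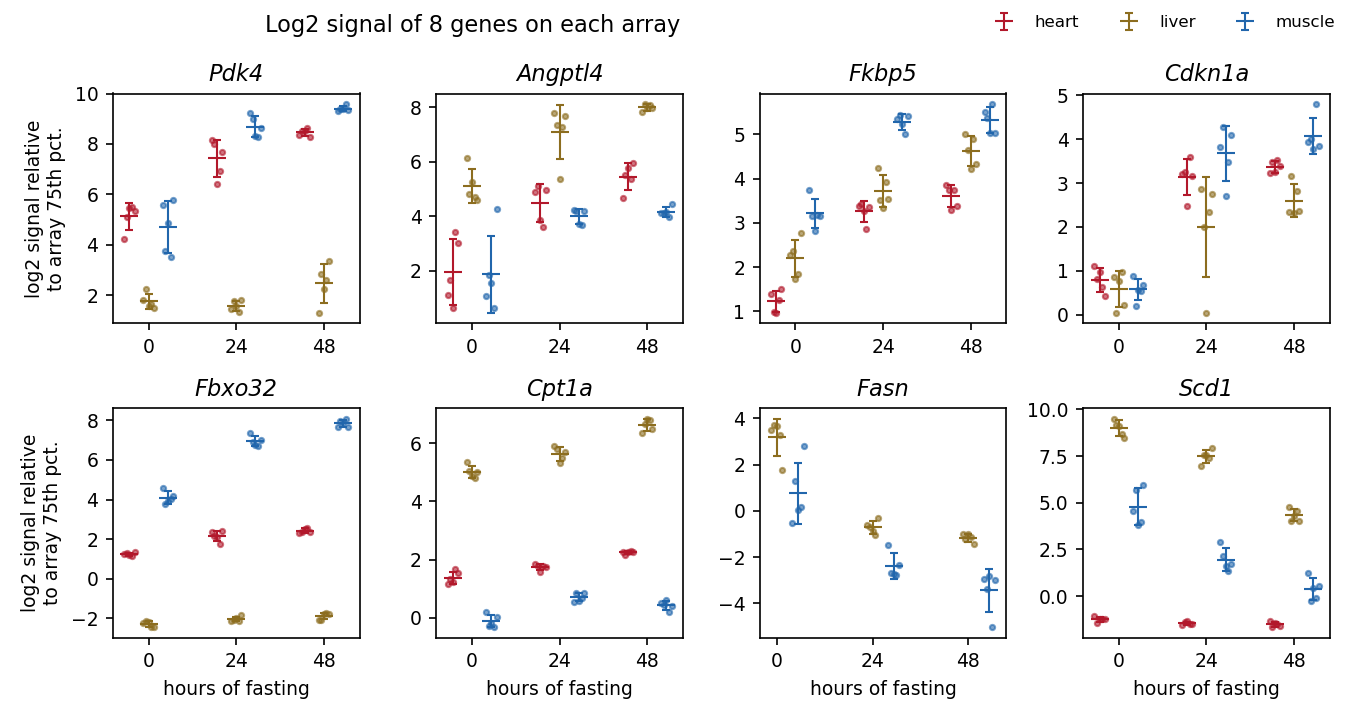
Level of Pdk4, Angptl4, Fkbp5, Cdkn1a, Fbxo32, Cpt1a, Fasn and Scd1 on each array, in log2 units relative to the array's 75th percentile, by tissue and hours of fasting. Points are arrays and bars are means ± SD (n = 5). Pdk4 went from 5.13 to 7.43 in heart within 24 h, and Fasn from 3.18 to -0.71 in liver.

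In the liver, the lists of fatty acid and cholesterol synthesis were lower after 24 h of fasting and that of drug-metabolising P450 enzymes higher, calls that did not hold with an estimated correlation. Fasn, fatty acid synthase (chromosome 11, 120667666 to 120667725), went from 3.18 ± 0.81 to -0.71 ± 0.28 (SD, n = 5), a 14.8-fold lower level with an adjusted p of 1.02e-06. Cyp2b9, a P450 enzyme (chromosome 7, 26983484 to 26983543), went from -1.65 ± 0.71 to 4.04 ± 0.64, a 51.4-fold rise with an adjusted p of 4.01e-07. The largest rises were Cyp2b9 (5.68 ± 0.38, 5.72 by slide), Cyp2b10 (5.26, 5.25 by slide), the stress gene Gadd45b (4.52, 4.64 by slide), Akr1b7 (3.67, 3.58 by slide), Mt2 (3.30, 3.38 by slide) and Msmp (3.06, 3.35 by slide). The largest falls were Fasn (-3.89 ± 0.30, -3.91 by slide), Thrsp, a thyroid hormone-responsive gene of lipogenesis (-3.86, -3.93 by slide), the steroid enzyme Hsd3b5 (-3.84, -4.31 by slide), Prok1 (-3.77, -3.86 by slide), Fabp5 (-3.72, -3.85 by slide) and Serpina4-ps1 (-3.68, -3.92 by slide). Akr1b7 was well above background on 3 of 5 arrays and Msmp on 1 at 0 h, and Prok1 on 3 at 24 h. Cux2 was at least 3.36-fold higher and Mmp7 at least 2.37-fold higher, and Gngt1 was at least 7.4-fold lower and Serpina12 at least 3.1-fold lower.

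Core genes that rose in liver at 24 h were Fgf21, a fasting hormone of the liver (2.87, adjusted p = 0.0126, well above background on 1 of 5 arrays at 0 h), Angptl4 (1.99), Igfbp1, which binds insulin-like growth factors (1.66), Fkbp5 (1.51), Pck1, the gatekeeping enzyme of gluconeogenesis (1.34), and Cpt1a (0.63). Srebf1, the master regulator of lipogenesis (-2.87), and the desaturase Scd1 (-1.5) fell. G6pc (0.51) and Cdkn1a (1.42) passed in the pooled fit only, with adjusted p by slide of 0.141 and 0.131. Pdk4 (-0.19), Ppargc1a (-0.05), Fbxo32 (0.25) and Ucp3 (0.07) did not pass. Igf1 (-0.14) did not pass either in its brightest probe, while 3 of its 4 other probes fell, from -1.09 to -0.42. Fatty acid synthesis genes fell in 21 of 22, with Acacb at -3.12. The mean was -1.65 (-1.69 by slide; adjusted p = 4.47e-19, 0.128 if estimated). Cholesterol synthesis genes fell in 24 of 25, with Fdps at -3.23 and Mvd at -2.96. Their mean was -1.65 (-1.76 by slide; adjusted p = 2.8e-22, 0.2 if estimated). Drug-metabolising P450s rose in 18 of 25 and fell in 2 (19 and 3 over the list alone), with Por at 2.36 and Cyp2a4 at 2.04, and their mean was 1.12 (1.10 by slide; adjusted p = 3.71e-12, 0.2 if estimated). Fatty acid oxidation rose in 14 of 33 and fell in 3 (16 and 4 over the list alone), led by the omega-hydroxylases Cyp4a14 at 2.62 and Cyp4a10 at 2.32. The mean was 0.36 (0.38 by slide; adjusted p = 0.00215, 0.641 if estimated).

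Proteasome subunits rose in 25 of 32 in liver at 24 h (30 over the list alone), with a mean of 0.36 (0.37 by slide; adjusted p = 6.67e-13, 0.348 if estimated). Interferon response genes fell in 17 of 37 (23 over the list alone), with Oasl1 at -1.07 and Psmb9 at -0.89. The mean was -0.43 (-0.45 by slide; adjusted p = 6.28e-08, 0.348 if estimated). Collagen and matrix genes fell in 13 of 31 and rose in 1 (13 and 2 over the list alone), with Col3a1 at -1.20 and Col1a1 at -0.87, and their mean was -0.27 (-0.34 by slide; adjusted p = 0.000299, 0.348 if estimated). Fibroblast and stellate cell markers had a mean of -0.26 that did not pass (adjusted p = 0.089). Neither the gluconeogenesis list (mean 0.25, adjusted p = 0.0708) nor the ketone body list (mean -0.04, adjusted p = 0.921) passed at 24 h. In total 4565 of 17991 liver genes passed, 2410 up and 2155 down, with 488 at least 2-fold, and 3623 passed with slide as a block, 1792 up and 1831 down, and 2837 within the first slide alone, 1311 up and 1526 down. The share of rises was 52.8% in the main scaling, 69% with median scaling, which called only 2003 genes (1382 up, 621 down), and 38% in the authors' table, and median scaling moved the median of all liver genes by 0.12 at 24 h and 0.22 at 48 h on the log2 scale.

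At 48 h the lists of gluconeogenesis and amino acid breakdown passed in liver as well and fatty acid oxidation stood higher than at 24 h, calls that did not hold with an estimated correlation, and among genes the transcript of a steroid enzyme fell furthest. Hsd3b5 (chromosome 3, 98422576 to 98422635) went from 6.66 ± 0.29 to -2.5 ± 1.02 (SD, n = 5), a 572-fold lower level with an adjusted p of 7.08e-09, and was well above background on 3 of 5 arrays at 48 h. Fgf21 (chromosome 7, 52869305 to 52869364) went from -4.19 ± 1.35 to 0.51 ± 1.14 with an adjusted p of 0.000143, and was well above background on 1 of 5 arrays at 0 h and on all at 48 h. The largest rises were Mt2 (4.86, 5.07 by slide), Fgf21 (4.71 ± 0.76, 4.73 by slide), Rgs16, a regulator of G protein signalling (4.32, 4.74 by slide), Gadd45b (4.28, 4.57 by slide), Mt1 (4.24, 4.03 by slide) and Pip5k1a (4.07, 4.22 by slide), whose 2 other probes, at 0.25 and 0.01, did not pass. The largest falls were Hsd3b5 (-9.16 ± 0.43, -10.35 by slide), Serpina4-ps1 (-6.54, -7.13 by slide), Sqle (-5.53, -6.27 by slide), Car3 (-4.76, -5.80 by slide), Scd1 (-4.65, -4.96 by slide) and Aqp8 (-4.48, -4.92 by slide). Sult1e1, oestrogen sulfotransferase, was at least 25.7-fold higher and Cux2 at least 10.2-fold higher, and Prok1 was at least 12.2-fold lower and Klk1b24 at least 8.94-fold lower.

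Among core genes in liver at 48 h, Igfbp1 rose by 3.5, Angptl4 by 2.89, Fkbp5 by 2.42, Pck1 by 2.23, the coactivator Ppargc1a by 1.92 and Cpt1a by 1.61, and Fasn (-4.34) and Srebf1 (-4.22) fell. G6pc (0.72), Cdkn1a (2.02, 1.11 by slide) and Fbxo32 (0.40) passed in the pooled fit only, with adjusted p by slide of 0.194, 0.279 and 0.201. Pdk4 (0.71, adjusted p = 0.0542), Ucp3 (0.13) and Igf1 (-0.02) did not pass, and 1 of 4 other Igf1 probes fell (-0.79, adjusted p = 0.0224). Gluconeogenesis genes rose in 14 of 17, with Got1 at 2.36 and Slc37a4 at 1.48. The mean was 0.98 (0.97 by slide; adjusted p = 3.14e-06, 0.201 if estimated). Amino acid catabolism and urea cycle genes rose in 24 of 32 and fell in 3 (24 and 5 over the list alone), with Asl at 1.94, Oat at 1.76 and Tat at 1.38, and their mean was 0.62 (0.66 by slide; adjusted p = 1.28e-06, 0.201 if estimated). Fatty acid oxidation rose in 23 of 33 and fell in 1 (23 and 2 over the list alone), with Cyp4a14 at 3.82 and Ehhadh at 1.62. The mean was 0.81 (0.86 by slide; adjusted p = 6.2e-08, 0.412 if estimated). Ketone body genes stayed divided, with 3 rises and 4 falls of 8 and the dehydrogenase Bdh2 at -1.44, and the list did not pass (mean -0.15, adjusted p = 0.88). Cholesterol synthesis fell in 24 of 25 and fatty acid synthesis in 19 of 22 with 1 rise. The means were -2.33 (-2.61 by slide; adjusted p = 1.32e-16, 0.201 if estimated) and -1.71 (-1.82 by slide; adjusted p = 2.38e-10, 0.201 if estimated). P450s rose in 17 of 25 and fell in 4 (18 and 4 over the list alone), with Cyp2b9 at 4.01 and Cyp2c70 at -2.57, and their mean was 0.64 (0.58 by slide; adjusted p = 0.000296, 0.381 if estimated).

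All 32 proteasome subunits rose in liver at 48 h, and ribosome biogenesis genes rose in 27 of 41. The means were 0.50 (0.52 by slide; adjusted p = 2.87e-11, 0.368 if estimated) and 0.44 (0.48 by slide; adjusted p = 3.14e-06, 0.45 if estimated). Interferon response genes fell in 35 of 37, with Ifi27l2a at -1.95 and Rtp4 at -1.59, and all 7 MHC class II genes fell, with H2-Ab1 at -1.46. Their means were -0.97 (-1.02 by slide; adjusted p = 3.89e-13, 0.246 if estimated) and -1.52 (-1.64 by slide; adjusted p = 0.000736, 0.348 if estimated). Macrophage markers fell in 12 of 17 and rose in 2 (14 and 2 over the list alone), with Aif1 at -1.36 and the scavenger receptor Cd163 at least 1.54-fold higher (adjusted p by slide 0.0507). Their mean was -0.34 (-0.35 by slide, adjusted p = 0.059 there; pooled adjusted p = 0.0167, 0.646 if estimated). Collagen genes fell in 24 of 31 and rose in 3, with Col3a1 at -2.70 and Col1a1 at -2.24, and the fibroblast and stellate markers fell in 9 of 13 and rose in 2 (10 and 2 over the list alone), with Lrat at -1.28. The means were -0.74 (-0.93 by slide; adjusted p = 9.67e-08, 0.201 if estimated) and -0.83 (-1.05 by slide; adjusted p = 0.000921, 0.325 if estimated). Hepatocyte markers did not pass, with a mean of 0.10 (adjusted p = 0.476). In total 8761 liver genes passed, 4629 up and 4132 down, with 1650 at least 2-fold, and 4660 with slide as a block, 2255 up and 2405 down. The share of rises was 52.8% in the main scaling and 76% with median scaling.

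Between 24 and 48 h, 4587 liver genes changed, 2374 up and 2213 down. The rises were largest for Sult1e1 (3.61, 4.19 by slide), the cytokine Il20 (3.37, 3.79 by slide) and Slc6a21 (3.11, 3.53 by slide), and the largest falls Hsd3b5 (-5.32, -6.03 by slide), Cyp2c55 (-5.10, -5.84 by slide), Scd1 (-3.15, -3.33 by slide) and Slco1a1 (-2.90, -3.26 by slide). Il20 and Slc6a21 were well above background on 1 of 5 arrays at 24 h, and Hsd3b5 on 3 at 48 h. Amino acid catabolism rose in 22 of 32 and fell in 1, with a mean of 0.53 (0.55 by slide; adjusted p = 2.55e-11, 0.131 if estimated). Fatty acid oxidation rose in 24 of 33, with a mean of 0.45 (0.48 by slide; adjusted p = 6.07e-10, 0.356 if estimated). Interferon response genes fell in 22 of 37, with a mean of -0.54 (-0.57 by slide; adjusted p = 9.05e-11, 0.31 if estimated). In the slide block 2854 genes passed, 1392 up and 1462 down, and within the second slide alone 2019, 1037 up and 982 down. Rises made up 51.8% of the calls in the main scaling and 67.5% with median scaling, which called 1952.

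**Figure D3:**
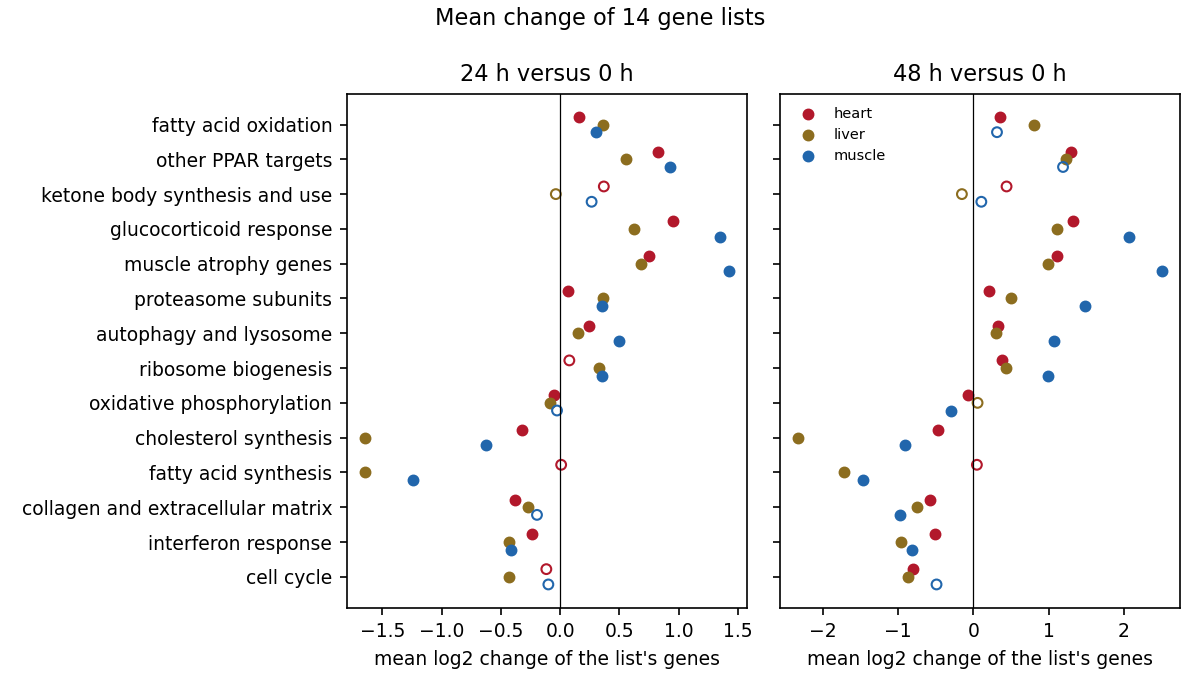
Mean log2 change of 14 gene lists after 24 and 48 h of fasting against 0 h, by tissue. Each point is the mean over the tested members of a list, and filled points passed the list test. Oxidative phosphorylation in liver at 24 h, at -0.08, turned to 0.04 with median scaling. Proteasome subunits reached 1.48 in muscle at 48 h, against 0.50 in liver and 0.21 in heart.

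Muscle at 24 h raised ubiquitin ligases and Pdk4 and lowered a kinase of NAD synthesis. The lists of glucocorticoid response and fatty acid synthesis moved up and down with them, but no list call in muscle held with an estimated correlation. Depp1, an autophagy regulator induced by FOXO factors (chromosome 6, 116602564 to 116602623), went from -0.84 ± 1.05 to 5.41 ± 0.82 (SD, n = 5), a 76.1-fold rise with an adjusted p of 2.22e-06. Fbxo32, the ubiquitin ligase atrogin-1 (chromosome 15, 58011752 to 58011811), went from 4.10 ± 0.31 to 6.95 ± 0.25, a 7.23-fold rise with an adjusted p of 3.33e-07. Nmrk2, nicotinamide riboside kinase (chromosome 10, 80662033 to 80662092), went from 6.93 ± 0.14 to 1.66 ± 1.15, a 38.7-fold lower level with an adjusted p of 4.54e-06. The largest rises were Depp1 (6.25 ± 0.47, 6.49 by slide), Ddit4, an inhibitor of mTORC1 (4.18, 4.01 by slide), Pdk4 (3.99, 4.14 by slide), Acot1 (3.75, 4.28 by slide), Slc25a34 (3.54, 3.86 by slide) and Cebpd (3.33, 3.37 by slide). The largest falls were Nmrk2 (-5.27 ± 0.43, -5.36 by slide), Tmem45b (-3.65, -3.21 by slide), Aldh1a7 (-3.39, -3.43 by slide), Fasn (-3.15, -3.05 by slide), Scd1 (-2.84, -2.58 by slide) and Mrap (-2.79, -2.49 by slide). At 24 h Tmem45b was well above background on 2 of 5 arrays and Aldh1a7 on 3. Tmem132e was at least 5.64-fold higher and Doc2b at least 5.24-fold higher. Gys2, the liver glycogen synthase, and Orm1, a liver plasma protein, were at least 4.43-fold and 4.11-fold lower. On 24 h replicates 2 and 5 the hepatocyte marker score (2.21, 2.28) exceeded every 0 h array but replicates 1 and 5. Of 15 hepatocyte markers, 1 fell and 14 did not pass (0 over the list alone), and their mean was -1.03 (-1.35 by slide; adjusted p = 0.0417, 0.82 if estimated).

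Core genes that rose in muscle at 24 h were Cdkn1a (3.11), Trim63 (3.05 ± 0.18, 3.22 by slide), Fbxo32 (2.86 ± 0.15, 2.92 by slide), Angptl4 (2.13), Fkbp5 (2.08), Ucp3 (1.99) and Cpt1a (0.82), and Srebf1 (-1.52), Igf1 (-1.23) and Ppargc1a (-0.53) fell, while another Ppargc1a probe, at -0.61, did not pass (adjusted p = 0.0574). Myostatin, Mstn, a brake on muscle growth, was at 0.42 (adjusted p = 0.0453, and 0.0907 by slide). G6pc (-0.41) and Pck1 (-0.20) did not pass. Muscle atrophy genes rose in 24 of 26, with a mean of 1.42 (1.52 by slide; adjusted p = 7.09e-18, 0.371 if estimated). Glucocorticoid response genes rose in 20 of 25 and fell in 1, with Arrdc2 at 3.25, and their mean was 1.35 (1.32 by slide; adjusted p = 8.67e-13, 0.371 if estimated). Autophagy genes rose in 22 of 42 (26 up and 1 down over the list alone), with Gabarapl1 at 1.78 and the initiating kinase Ulk1 at 1.40, and their mean was 0.49 (0.55 by slide; adjusted p = 9.33e-07, 0.6 if estimated). Proteasome subunits rose in 21 of 32 (25 over the list alone), with Psmd11 at 0.80, and ribosome biogenesis genes rose in 28 of 41 and fell in 1 (29 and 1 over the list alone), with Ddx21 at 0.99. The means were 0.35 (0.41 by slide; adjusted p = 6.47e-11, 0.605 if estimated) and 0.35 (0.41 by slide; adjusted p = 3.7e-09, 0.6 if estimated).

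Fatty acid synthesis genes fell in 13 of 20 in muscle at 24 h and rose in 2 (14 and 2 over the list alone), with Slc25a1 at -2.72 and Elovl6 at -2.65. The mean was -1.24 (-1.19 by slide; adjusted p = 9.52e-07, 0.6 if estimated). White adipocyte markers fell in 2 of 12 (3 over the list alone), with a mean of -1.07 (-0.76 by slide, adjusted p = 0.094 there; pooled adjusted p = 0.00645, 0.75 if estimated). Cholesterol synthesis fell in 15 of 22 and rose in 1 (17 and 2 over the list alone), with Sqle at -2.46 and Dhcr7 at -1.62, and the mean was -0.63 (-0.65 by slide; adjusted p = 7.86e-09, 0.371 if estimated). Interferon response genes fell in 12 of 34 (16 over the list alone), with Usp18 at -0.89, and their mean was -0.42 (-0.40 by slide; adjusted p = 2.96e-06, 0.605 if estimated). Macrophage markers fell in 2 of 13, with a mean of -0.45 (-0.52 by slide; adjusted p = 0.0345, 0.741 if estimated). Slow-fibre genes had a mean of 0.85 that did not pass (adjusted p = 0.226), against 1.36 by slide (adjusted p = 0.0422), and scored 4.07 on replicate 3 of 24 h. White adipocyte markers, Fasn and Scd1 were highest on 0 h replicates 5 and 2 (3.90 and 3.05, 2.79 and 1.31, 5.95 and 5.67). Whether fat in these samples adds to the falls stays open. In total 4284 of 19218 muscle genes passed, 2729 up and 1555 down, with 525 at least 2-fold, 4231 with slide as a block, 2599 up and 1632 down, and 3099 within the first slide, 1932 up and 1167 down. Without the 5 muscle arrays highest in hepatocyte markers 1331 passed. The share of rises was 63.7% in the main scaling, 51.6% with normexp and quantile, 51.5% with the percentile over detected probes and 43.8% in the authors' table.

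**Figure D4:**
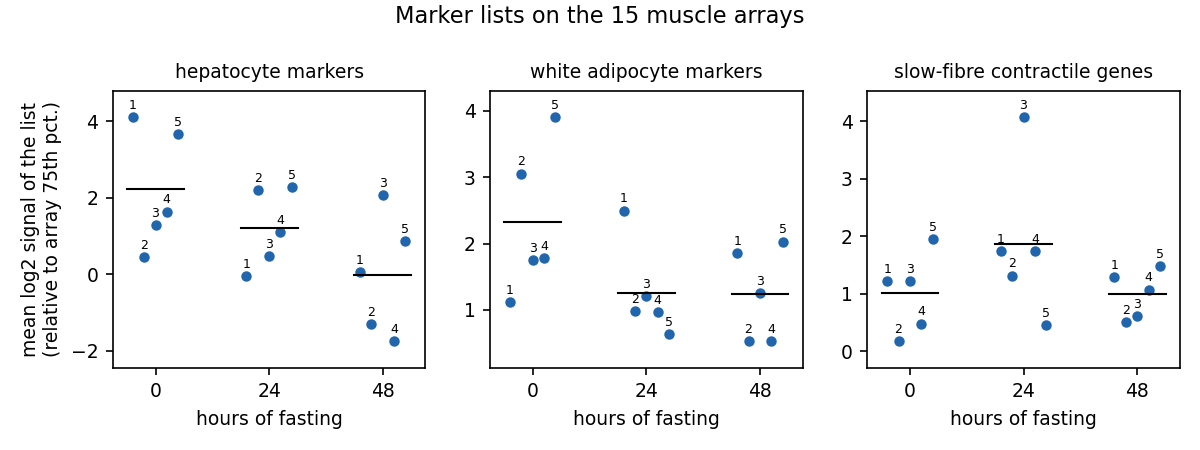
Mean log2 level of hepatocyte, white adipocyte and slow-fibre genes on each muscle array, relative to the array's 75th percentile, by hours of fasting. Points are arrays (n = 5 per time), numbered by replicate, and lines are means. Hepatocyte markers reached 4.11 and 3.67 on replicates 1 and 5 of 0 h, and slow-fibre genes 4.07 on replicate 3 of 24 h.

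By 48 h muscle had the most genes called of the 3 tissues, with all proteasome subunits raised and oxidative phosphorylation lower as a list, although neither list call held with an estimated correlation. Nmrk2 reached -0.95 ± 0.56 (SD, n = 5), 236-fold below 0 h, and Mt2 went from 3.17 ± 0.38 to 9.0 ± 0.39, a 57.2-fold rise. The largest rises were Depp1 (6.37, 6.96 by slide), Mt2 (5.84, 5.92 by slide), Acot1 (5.70, 7.01 by slide), Ddit4 (5.55, 5.11 by slide), Pip5k1a (5.22, 5.36 by slide) and Maff (5.20, 5.96 by slide). The largest falls were Nmrk2 (-7.88, -8.10 by slide), Fam78a (-5.95, -6.75 by slide), Pwwp3b (-5.57, -6.38 by slide), Itgb6 (-5.43, -6.28 by slide), Tmem233 (-5.27, -6.13 by slide) and Mdga1 (-5.25, -6.20 by slide). Maff was well above background on 4 of 5 arrays at 0 h, and at 48 h Pwwp3b was on 1, Itgb6 on 2 and Fam78a and Mdga1 on 3. Other probes of Pip5k1a rose by only 1.315 and 0.884, and another of Itgb6 fell by 3.822. Doc2b was at least 63.6-fold higher and Tmem132e at least 24.3-fold higher, and Aldh1a7 was at least 17-fold lower and Ankrd34a at least 10.1-fold lower. Core genes that rose were Pdk4 (4.70), Trim63 (3.93), Fbxo32 (3.76), Cdkn1a (3.50), Ucp3 (2.75), Angptl4 (2.29), Fkbp5 (2.11) and Mstn (0.81), and Scd1 (-4.42), Fasn (-4.2), Srebf1 (-2.60) and Igf1 (-1.73) fell. Cpt1a (0.55) passed in the pooled fit only, with an adjusted p by slide of 0.0767. Pck1 (0.41), Ppargc1a (0.05) and G6pc (-0.44) did not pass, but the other Ppargc1a probe did (0.75, adjusted p = 0.00748). Fasn and Srebf1 were well above background on 3 of 5 arrays at 48 h.

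All 32 proteasome subunits rose in muscle at 48 h, with Psmd11 at 2.31 and Psmc4 at 2.01. The mean was 1.48 (1.62 by slide; adjusted p = 1.14e-15, 0.6 if estimated). Muscle atrophy genes rose in 23 of 26 and fell in 1, with Foxo3 at least 9.25-fold higher (1.708 on another probe), and their mean was 2.5 (2.74 by slide; adjusted p = 3.33e-08, 0.6 if estimated). Glucocorticoid response genes rose in 22 of 25 and fell in 1 (22 and 2 over the list alone), with a mean of 2.07 (1.98 by slide; adjusted p = 2.58e-06, 0.6 if estimated). Autophagy genes rose in 34 of 42 and fell in 2, with Gabarapl1 at 3.64 and the protease Ctsl at 2.73, and their mean was 1.07 (1.21 by slide; adjusted p = 3.71e-07, 0.6 if estimated). Ribosome biogenesis genes rose in 37 of 41 and fell in 2, with Gnl3 at 2.71. The mean was 1.0 (1.14 by slide; adjusted p = 7.31e-10, 0.6 if estimated). Ribosomal proteins rose in 66 of 73 (68 over the list alone), with Rpl3 at 0.74, and stood 0.29 above the other genes. Their mean was 0.33 (0.36 by slide; adjusted p = 2.16e-07, 0.758 if estimated). Oxidative phosphorylation fell in 47 of 68 and rose in 1, with Ndufc2 at -0.86 and Cyc1 at -0.73, and its genes stood at -0.34 against the others. The mean was -0.30 (-0.30 by slide; adjusted p = 4.74e-07, 0.758 if estimated), while slow-fibre genes had a mean of -0.02 that did not pass.

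Fatty acid synthesis fell in 15 of 20 in muscle at 48 h and rose in 2 (16 and 2 over the list alone), with Pnpla3 at -2.70, and its mean was -1.47 (-1.34 by slide; adjusted p = 0.00152, 0.605 if estimated). The white adipocyte marker mean, -1.08, did not pass (adjusted p = 0.106). Cholesterol synthesis fell in 19 of 22 and rose in 2, with Sqle at -2.52 and squalene synthase Fdft1 at 2.64. The mean was -0.91 (-0.98 by slide; adjusted p = 2.31e-05, 0.565 if estimated). Collagen and matrix genes fell in 24 of 39 and rose in 4, with Col3a1 at -3.47, Col1a1 at -3.24 and Postn at -2.68, and their mean was -0.97 (-1.28 by slide; adjusted p = 7.91e-05, 0.721 if estimated). Fibroblast and stellate cell markers fell in 7 of 13 and rose in 2, with a mean of -0.98 that did not pass (adjusted p = 0.0764; -1.30 by slide, adjusted p = 0.0613). Tendon and cartilage markers had 4 falls of 9, with the tendon factor Scx at -2.42, and a mean of -1.05 that did not pass (adjusted p = 0.0945). Interferon response genes fell in 28 of 34 and rose in 1 (28 and 2 over the list alone), with Igtp at -2.14, and the mean was -0.81 (-0.76 by slide; adjusted p = 2.31e-05, 0.689 if estimated). Macrophage markers fell in 4 of 13 and rose in 1 (3 and 1 over the list alone), with a mean of -0.51 that did not pass (adjusted p = 0.224). Denervation and myogenic regulators did not pass as a list (adjusted p = 0.831, mean 0.27, median -0.14), with Runx1 at 4.51 and Gadd45a at 3.56 against the myogenic factor Myod1 at -2.07. Hepatocyte markers fell in 9 of 15 (8 over the list alone), with Ttr at -3.81, and their mean was -2.24 (-3.05 by slide; adjusted p = 0.0294, 0.808 if estimated). In total 12687 muscle genes passed, 6953 up and 5734 down, with 3634 at least 2-fold, and 9565 with slide as a block, 5242 up and 4323 down. Without the 5 muscle arrays highest in hepatocyte markers 11297 passed. The share of rises was 54.8% in the main scaling, 41% in the authors' table and 36.4% with the percentile over detected probes, which moved the median of all muscle genes by -0.14 and -0.23.

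Between 24 and 48 h, 10045 muscle genes changed, 5730 up and 4315 down. The rises were largest for Dync1i1 (3.80, 4.25 by slide), Mt2 (3.68, 3.73 by slide), Pip5k1a (3.61, 3.70 by slide) and Doc2b (3.60, 3.88 by slide), and the largest falls Mybph (-4.32, -4.90 by slide), Pwwp3b (-4.12, -4.60 by slide), Tmem233 (-4.01, -4.53 by slide) and Itgb6 (-3.77, -4.28 by slide). Dync1i1 was well above background on 2 of 5 arrays at 24 h, and Pwwp3b on 1 and Itgb6 on 2 at 48 h. Other probes of Pip5k1a rose by 0.777 and 0.712, and another of Itgb6 fell by 1.994. All 32 proteasome subunits rose, with a mean of 1.13 (1.21 by slide; adjusted p = 2e-18, 0.6 if estimated). Ribosomal proteins rose in 67 of 73 and oxidative phosphorylation fell in 46 of 68, with means of 0.31 (0.32 by slide; adjusted p = 7.31e-10, 0.723 if estimated) and -0.27 (-0.27 by slide; adjusted p = 2.59e-09, 0.723 if estimated). Collagen genes fell in 24 of 39 and tendon markers in 5 of 9, with means of -0.78 (-0.97 by slide; adjusted p = 1.11e-05, 0.692 if estimated) and -1.24 (-1.59 by slide; adjusted p = 0.0136, 0.723 if estimated). In the slide block 8757 genes passed, 4892 up and 3865 down, and within the second slide alone 8786, 4961 up and 3825 down. Rises made up 57% of calls in the main scaling, 43.2% in the authors' table and 35.2% with the percentile over detected probes, whose shift of the median was -0.18.

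Most genes called at 24 h were called again at 48 h in the same direction. These were 3389 genes in heart (1702 up, 1687 down; 83.4% of the 24 h calls), 3682 in liver (2000 up, 1682 down; 80.7%) and 3893 in muscle (2537 up, 1356 down; 90.9%). Independent lists of the same lengths would share 408.6 rises and 465.7 falls in heart, 620.1 and 494.9 in liver, and 987.3 and 464 in muscle. Both times were set against the same 0 h arrays. In 20 simulations of unchanged groups against those controls, 0 genes at most were shared in each tissue. Unchanged groups give few calls by design, so this count cannot show how far common controls add to the overlap. Across genes the covariance of the changes was 0.112, 0.222 and 0.319 in heart, liver and muscle, against 0.00956, 0.0145 and 0.0186 in the simulations. The correlation was 0.802, 0.798 and 0.808, against 0.502, 0.499 and 0.5 there, so common controls alone give a sizeable correlation. With the controls split between the comparisons, a median of 1932, 2121.5 and 2428.5 genes were shared over 20 splits. Independent lists would then share 408.8, 513.6 and 864.2. The covariance was then 0.104, 0.21 and 0.3, and the correlation 0.7, 0.716 and 0.716. Rises made up 54.3% of the shared liver calls in the main scaling, 38.6% in the authors' table and 70.3% with median scaling, and 65.2% of those of muscle, against 51.8% with normexp and quantile, 43.9% in the authors' table and 50.8% with the percentile over detected probes.

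Of 15711 genes tested in each, 479 changed the same way in heart, liver and muscle at 24 h, 327 up and 152 down, where independent lists would share 38.2 and 15.9. The 24 h number was 195 with median scaling and 222 without the 5 muscle arrays highest in hepatocyte markers. At 48 h they were 2436, 1412 up and 1024 down, against 357.4 and 216.6. With slide as a block the 48 h number was 941. Rises by 24 h were led by Mt2 (2.84 in heart, 3.30 in liver, 2.16 in muscle), Angptl4 (2.53, 1.99, 2.13), Cyp2b10 (1.93, 5.26, 4.18), Slc10a6 (1.67 in heart, 2.17 in muscle), Pip5k1a (2.03, 2.57, 1.61), Acot1 (1.71, 1.57, 3.75), Fkbp5 (2.03, 1.51, 2.08) and Mt1 (1.49, 2.85, 2.03). In muscle Cyp2b10 and Slc10a6 had adjusted p by slide of 0.0755 and 0.0528 and were well above background on 2 of 5 arrays at 0 h. In liver Slc10a6 was not well above background at 0 h and has no fold. Other Pip5k1a probes did not pass (-0.03 and 0.13 in heart, 0.23 and 0.06 in liver, 0.17 in muscle), except 1 in muscle (0.54). Leading falls included the cytokine signal inhibitor Cish (-1.05, -2.42, -2.12), Dhcr7 of cholesterol synthesis (-0.92, -2.28, -1.62), the collagen chaperone Serpinh1 (-0.90, -1.07, -1.10), cyclin D1, Ccnd1 (-0.96, -0.89, -1.45), Nrep (-1.36, -2.12, -1.14) and Spon2 (-1.58, -0.86, -1.68). Sqle completed these falls, at least 2.09-fold lower in heart and at -2.68 in liver and -2.46 in muscle. At 48 h Acot5, a thioesterase (2.33, 2.83, 3.35), joined the leading rises, although its second probe stood at -0.09 in heart and 0.02 in muscle. Col3a1 (-2.29, -2.70, -3.47), Ces2e (at least 2.69-fold lower in heart and 2.38-fold in muscle, -2.05 in liver), Cd209f (at least 1.82-fold lower in heart, -1.89 in liver, -2.20 in muscle) and Mboat1 (at least 2.13-fold lower in heart, -1.68 in liver, -2.86 in muscle) joined the falls. So did Mest and Cdca8, a mitotic gene that was at least 1.56-fold, 4.33-fold and 3.32-fold lower, with a second liver probe of Cdca8 at -0.45 that did not pass. The share of rises among common genes was 68.3% at 24 h (46.8% in the authors' table) and 58% at 48 h (40.5% in the authors' table, 41.6% with the percentile over detected probes and 73.8% with median scaling).

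Responses also differed between tissues by a test of the difference. Liver and heart differed in 3401 of 16053 genes at 24 h (1855 higher in the liver response, 1546 lower) and 5603 at 48 h (3013 and 2590). Liver and muscle differed in 2996 of 16408 (1330 and 1666) and 9052 (3796 and 5256), and heart and muscle in 1553 of 17475 (518 and 1035) and 8729 (3363 and 5366). With slide as a block the 48 h numbers were 2962, 5917 and 5319. Levels between tissues, hybridised on separate slides, were not compared. Relative to heart, the liver response at 24 h was higher for Rgs16 (difference 4.11, adjusted p = 0.000669), Tfrc (3.71, adjusted p = 2.01e-08) and Gadd45b (3.65), and lower for Thrsp (-4.10, adjusted p = 8.25e-10), Fabp5 (-3.68) and Acacb (-3.36), and at 48 h it was higher for Tfrc (4.82) and lower for Klk1b26 (-5.12), Klk1b5 (-4.95) and Scd1 (-4.39). Well above background were Rgs16 on 2 of 5 arrays in heart at 24 h and, in liver at 48 h, Klk1b26 on 2 and Klk1b5 on 4 (3 in heart at 0 h). Where a group was not well above background the difference is a bound too, and the liver response at 48 h was at least 29.7-fold higher for Rgs16 and at least 30.5-fold higher for Cux2. Liver stood above muscle for Sult1e1 (at least 2.26-fold at 24 h and 31-fold at 48 h), Gadd45b (4.05 at 24 h), Aldh1a7 (3.08 at 24 h), Cux2 (at least 20.3-fold at 48 h) and Tfrc (5.52 at 48 h), and below it for Depp1 (-5.63 and -5.38), Chac1 (-4.32 at 24 h), Pdk4 (-4.18 at 24 h), Tmem132e (at least 29.7-fold at 48 h) and Egln3 (-5.26 at 48 h). Heart stood above muscle for Cdo1 (at least 9.78-fold at 24 h), Slc25a1 (3.0 at 24 h), Nmrk2 (3.65 and 8.62), Ttr (at least 25.7-fold at 48 h) and Pwwp3b (4.98 at 48 h), and below it for Depp1 (-4.87 and -4.60), Plekhh1 (-3.42 at 24 h), Ddit4 (-3.19 and -4.68) and Egln3 (-6.25 at 48 h). In muscle Aldh1a7 was well above background on 3 of 5 arrays at 24 h, Pwwp3b on 1 at 48 h and Plekhh1, Sult1e1 and Cux2 on 4 at 0 h, and Ttr was on 3 and, in heart, Cux2 on 4 at 48 h. Ttr is a hepatocyte marker, and these markers as a list differed alike between heart and muscle at 48 h (2.67, adjusted p = 0.0441, 0.758 if estimated), with high values on muscle replicates 1 and 5 of 0 h. In heart they rose in 2 of 6 and fell in 1, with a mean of 0.77 that did not pass (adjusted p = 0.197), although their score lay between -0.569 and -0.233 on the 0 h arrays and between 0.127 and 0.453 at 48 h.

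Gene lists differed between tissues too. Proteasome subunits rose less in heart than in muscle at 48 h (difference -1.27, adjusted p = 5.35e-21, 0.342 if estimated) and less in liver than in muscle (-0.98, adjusted p = 2.53e-12, 0.509 if estimated). Fatty acid synthesis stood lower in the liver response than in that of heart at 24 h (-1.49, adjusted p = 2.31e-19, 0.0326 if estimated) and at 48 h (-1.63, adjusted p = 1.8e-12, 0.172 if estimated), and its heart mean of 0.01 at 24 h did not pass (adjusted p = 0.197). Cholesterol synthesis fell further in liver than in heart, at 24 h (-1.30, adjusted p = 5.04e-17, 0.183 if estimated) and at 48 h (-1.86, adjusted p = 6.83e-16, 0.183 if estimated). Muscle atrophy genes differed between heart and muscle at 48 h (-1.46, adjusted p = 1.68e-05, 0.465 if estimated), and gluconeogenesis between liver and heart (0.92, adjusted p = 0.000147, 0.315 if estimated). The share of genes higher in the first tissue changed with the scaling. It was 54.5% for liver against heart at 24 h (36.7% in the authors' table), 41.9% for liver against muscle at 48 h (53.7% in the authors' table and 59.3% with the percentile over detected probes), 33.4% for heart against muscle at 24 h (45.4% with normexp and quantile, 43.7% with quantile, 56.4% in the authors' table) and 38.5% at 48 h (49.6%, 49.6% and 57.6%, and 60.6% with the percentile over detected probes). Over all tissues and times 182 list calls were made, and 7 of them held with an estimated correlation, namely the muscle atrophy list in heart and in liver at 24 and 48 h, the white adipocyte markers in heart at 24 h and the NRF2 list in heart at 48 h and between 24 and 48 h. With slide as a block too, neither liver call held (adjusted p = 0.0883 at both times).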

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

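The tests of liver transcripts in muscle, of same-numbered arrays and of clock genes were chosen only after the results were seen, except that of equal positions on the 2 slides, and the splits of the arrays were planned. Of 201 groups of 5 arrays, 10 held an array outside Dixon's critical value of 0.71, where chance gives about 1 in 20 groups, or 10.1. Fkbp5 in heart at 24 h stood at 2.85 on replicate 4 against 3.27 to 3.42 (ratio 0.736), and Ucp3 in heart at 48 h at 1.80 on replicate 1 against 2.09 to 2.18 (0.757). Fasn in liver at 0 h stood at 1.77 on replicate 5 against 3.27 to 3.72 (0.768), and Angptl4 in liver at 24 h at 5.35 on replicate 3 against 7.28 to 7.78 (0.792). In muscle, Srebf1 at 24 h stood at -1.13 on replicate 4 against -2.12 to -1.88 (0.753). On replicate 4 of 48 h, Cdkn1a stood at 4.81 against 3.79 to 4.0 (0.794), Fasn at -5.04 against -3.38 to -2.80 (0.743) and Pdk4 at 9.59 against 9.32 to 9.39 (0.743). The mean of erythroid markers in liver at 24 h was 3.74 on replicate 4 against 4.01 to 4.03 (0.942), and that of endothelial markers in muscle at 24 h was 2.12 on replicate 3 against 1.79 to 1.87 (0.753).

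Responses differed between tissues in 3401 genes (liver and heart, 24 h), 5603 (48 h), 2996 (liver and muscle, 24 h), 9052 (48 h), 1553 (heart and muscle, 24 h) and 8729 (48 h). Shuffling the tissue labels gave as many genes in 1 of 100 splits, the real one, in each of these 6 comparisons. That is the smallest share that 100 splits can give. The shuffles treat arrays as independent, although arrays of the same number stood apart together in the tissues. The real split called 3397, 5598, 2991, 9023, 1551 and 8716 genes on the genes common to all splits, and the highest other 3, 590, 315, 2594, 0 and 4607. Other splits of the arrays within a tissue also reached the real number in 1 of 100, the real one, for all 9 comparisons. The real and the highest other numbers were 4062 and 53, 7960 and 3, and 3860 and 4 in heart, 4561 and 62, 8753 and 22, and 4588 and 459 in liver, and 4289 and 334, 12663 and 9, and 10032 and 3081 in muscle, for 24 h against 0 h, 48 h against 0 h and 48 h against 24 h.

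Liver transcripts stood high on some muscle arrays. The hepatocyte marker mean was 4.11 and 3.67 on replicates 1 and 5 of 0 h, against 0.44 to 1.64 on the other 0 h arrays. Of 183 liver genes outside the lists, whose median lay 1.64 log2 units above the group mean on replicate 1, 88% followed the marker mean across muscle arrays at r over 0.5, against at most 14.2% in 1000 random sets, and their excess rose with the liver level at a slope of 1.17 (r = 0.931 across 178 genes, which are not independent replicates). Array position is argued against, since random sets of other genes of the same muscle level lay at most 0.29 above the group mean on that array. Liver RNA carried into these samples is a candidate explanation, and it may account for the lower Gys2, Orm1 and Ttr in fasted muscle.

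Arrays of the same number stood apart from their group together in the 3 tissues. Their distance along the fasting response correlated between heart and liver (r = 0.921, permutation p = 3e-04, adjusted 9e-04; rho = 0.818, permutation p = 0.00338, adjusted 0.00969; n = 15), heart and muscle (r = 0.883, permutation p = 0.00115, adjusted 0.00172; rho = 0.761, permutation p = 0.00646, adjusted 0.00969) and liver and muscle (r = 0.884, permutation p = 0.00624, adjusted 0.00624; rho = 0.75, permutation p = 0.0104, adjusted 0.0104), a family of 3 pairs with a mean r of 0.896. Without the 2 arrays farthest from the median, replicate 4 of 48 h and replicate 1 of 24 h, r was 0.814, 0.715 and 0.669, and within slides and times it was 0.918, 0.889 and 0.867. Within the 5 arrays of 0 h r was 0.30, -0.213 and -0.328, which was not tested. A stage of fasting reached by each mouse is consistent with this, if equal numbers mark a mouse, which the labels do not say. Position on the slide was the same in every tissue and cannot be told apart from it, since arrays at equal positions on the 2 slides had r = 0.726 over 7 positions (exact p = 0.0992; rho = 0.393, exact p = 0.396; r = 0.549 without the 2 farthest).

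Of the clock genes of known phase, 5 of 8 tested passed at 48 h in heart, 8 of 10 in liver and 10 of 11 in muscle. If sampling at another time of day were the cause, and genes sorted into the same phase moved alike, called genes would move to one side of the cycle. In muscle 50% did, 5 of 10 called, with Ciart at 6.23 and Dbp at -1.88, which argues against it as the whole cause. In liver 87.5% did, 7 of 8, with Nr1d1 at 1.62, Dbp at 1.35 and Npas2 at -2.09, so a later or earlier clock time may be part of the liver values. In heart 80%, 4 of 5, were too few to tell, and fasting itself stays open as a cause in every tissue.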

How the results depend on the processing

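Alternatives added after the results were seen were the percentile over detected probes, the fits within a slide, the slide block of named genes, lists and between-tissue, shared and overlapping results, the slide block of lists with an estimated correlation, the fits without sets of muscle arrays, median scaling of named, shared and overlapping genes, and leaving out each array for shared and overlapping genes. The others were planned. Signal over background limits dim genes, which have only bounds. Where no cause is named, the cause was not tested.

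Stricter thresholds lower the counts by construction. At an adjusted p under 0.01, 24 h against 0 h had 2264 genes in heart, 2360 in liver and 2242 in muscle, 48 h against 24 h had 1749 in heart and 2491 in liver, and responses at 24 h differed in 1834 genes between liver and heart, 1548 between liver and muscle and 663 between heart and muscle. Genes common to all tissues were then 178 and 1500 at 24 and 48 h, and those shared by both times 1930, 1986 and 2102 in heart, liver and muscle. At a fold of 2 or more the 3 comparisons had 222, 765 and 165 genes in heart, 488, 1650 and 570 in liver, and 525, 3634 and 1673 in muscle. Differences at 24 and 48 h were 381 and 1165 between liver and heart, 523 and 2783 between liver and muscle, and 269 and 2088 between heart and muscle, common genes 25 and 139, and genes shared by both times 203, 389 and 492.

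With slide, which is also the scan batch, as a block, 48 h against 0 h had 5010 genes in heart and 4660 in liver, 48 h against 24 h had 2854 in liver, responses at 48 h differed in 2962, 5917 and 5319 genes (liver and heart, liver and muscle, heart and muscle), and 941 genes were common to all tissues. The contrast of 48 h with 0 h then rests on the 24 h arrays alone as the link. Within the first slide liver had 2837 genes at 24 h, and within the second heart had 1489 and liver 2019 for 48 h against 24 h, with fewer arrays in each fit. Of the 4062, 4565 and 4284 genes called at 24 h in heart, liver and muscle, all kept their sign in the block, and so did 7895, 8740 and 12667 of those called at 48 h. Median scaling gave 2508 genes for heart and 1952 for liver at 48 h against 24 h, 2003 for liver at 24 h, 195 common genes at 24 h and 1755 liver genes shared by both times. Without a detection filter heart had 13723 at 48 h against 0 h and 7936 at 48 h against 24 h, and 250 genes were common at 24 h. All 45 arrays in one fit gave heart 2644 at 24 h and 2289 for 48 h against 24 h. Without the 5 muscle arrays highest in hepatocyte markers, muscle had 1331 genes at 24 h, liver and muscle differed in 1942, heart and muscle in 908, 222 genes were common and 1235 were shared by both times in muscle. Leaving out 5 other arrays gave a median of 1948 genes over 40 draws, with 10 draws as low as 1331.

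Of 182 list calls, 7 held with an estimated correlation, with 2, 2 and 1 lists called in heart, 1, 1 and 0 in liver and 0, 0 and 0 in muscle. With slide as a block and an estimated correlation they were 2, 2 and 1, then 0, 0 and 0, and 0, 0 and 0. The fry test, which does not compare a list with other genes, called 38 lists in heart and 33 in muscle at 48 h. The ribosomal protein list in liver at 48 h turned from up to down with normexp and quantile (-0.052, adjusted p = 0.0516) and with quantile (-0.047, adjusted p = 0.0292). Of the list calls 166 were kept with slide as a block, 168 in the authors' table, 161 with normexp and quantile and 164 with quantile.

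Among 594 results of named genes, the slide block kept 532 on the same side of the threshold and ended 56 calls, and the authors' table kept 575. Reversed values were small except for other probes in muscle of Per1 (-1.424 at 24 h, -4.626 at 48 h) and Rora (-0.737, -1.771), clock genes that rose in their brightest probe. The others were G6pc in heart at 24 h (-0.012 in the slide block), Igf1 in heart at 48 h (0.043, other probe), Ppargc1a in liver at 24 h (0.068, median scaling), Ucp3 in liver (-0.023 and -0.109, slide block), Igf1 in liver at 48 h (0.197, median scaling; 0.016, other probe), Pck1 in muscle at 24 h (0.012, slide block), Ppargc1a in muscle at 48 h (-0.198 normexp and quantile, -0.143 quantile, -0.277 authors' table, -0.182 percentile over detected probes), Pip5k1a in heart at 24 h (-0.034, other probe) and Acot5 in heart at 48 h (-0.087, other probe).

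Leaving out each replicate gave 3324 to 4350, 7101 to 8489 and 2761 to 3843 genes in heart, 3752 to 4645, 7942 to 8894 and 3590 to 4511 in liver, 3125 to 4556, 12095 to 12694 and 9088 to 10410 in muscle, and 402 to 502 and 2249 to 2532 common genes. Replicate numbers did not pair arrays across times within a tissue (r from -0.333 to 0.268). With the replicate block 3586, 7518 and 3154 genes passed in heart, 3794, 8140 and 3887 in liver and 3562, 12360 and 9406 in muscle. Across tissues, 33 of 45 comparisons of an array with those of another tissue at the same time gave the highest correlation for its own number. With array weights, a trended and robust variance, the percentile over detected probes and the authors' table every total within a tissue stayed within 1.5 times its main value, although falls alone went further, from 1555 to 2627 in muscle at 24 h in the authors' table and from 4315 to 7046 between 24 and 48 h with the percentile over detected probes.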

Other observations

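The iron genes, and the choice to set Myh7 against its list, were settled after their values were seen, while the tests within and between tissues were planned. Single genes of iron uptake, release and storage, which form no tested list, changed in heart and muscle. Tfrc, which takes up iron, fell in heart (-3.45 at 24 h, -3.47 at 48 h) and muscle (-2.02, -4.17) and stood at 0.25 in liver at 24 h, where it did not pass, before it rose by 1.35 at 48 h. The difference between liver and heart was 3.71 at 24 h (adjusted p = 2.01e-08) and 4.82 at 48 h. Hmox1, which frees iron from heme, rose in heart (1.15, 3.60) and muscle (1.49, 4.06), and its liver values of -0.08 and 0.60 did not pass. A second Hmox1 probe did not pass at 24 h in heart (0.28) or muscle (0.82). The ferritin light chain Ftl1, which stores iron, rose in heart (0.42, 0.74) and muscle (0.51, 1.18), and its liver values of 0.12 and 0.05 did not pass. The heavy chain Fth1 rose in liver (0.3, 0.32) as well as heart (0.14, 0.38). In muscle Fth1 was at 0.09 at 24 h, which did not pass, and rose by 0.35 at 48 h. The 2 chains were not tested against each other. The iron exporter Slc40a1 rose in heart (1.24, 1.09), in muscle (1.05, 0.77) and, at 24 h, in liver (0.61), and its blocker Hamp, the hormone hepcidin, rose by 1.05 in liver at 48 h (adjusted p = 0.0135).

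Among 18 cardiac contractile and stress genes in heart, the slow myosin Myh7 rose 21.6-fold at 48 h while Ankrd1 (1.59) and Nppa (1.13) rose too and 9 fell, and its adjusted p was 2.96e-08. No explanation of the iron or myosin values was tested.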
